A study of Dermatophagoides farinae with 4 samples.

How the data were processed

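Nuclei of untreated whole mites were measured in 3 snRNA libraries (replicates 1, 2 and 3) and 1 snATAC library, grouped by the submitters' sample titles. The snRNA files hold raw UMI counts per gene and barcode, not normalized, written by Cell Ranger 8.0.1 per the file headers. They came from the 10x Genomics 3' kit on nuclear RNA per the labels' protocols, and Cell Ranger and Seurat 4.1.0 are named, with no role, per the submitters' processing notes. The aligner, genome build and annotation are not given in the sources used here. Every deposited barcode holds at least 500 UMIs, so a minimum was applied before deposit, and shallower nuclei are outside these data. The snATAC file holds, per the file headers, counts of read pairs and fragments per barcode, with a mark for barcodes called nuclei. The tool version and the peak caller are not given in the sources used here.

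The libraries held 8452407, 16028945 and 12521558 UMIs, and the library and cluster sums used in the tests 31920 to 2351751 UMIs. Levels near 1 CPM therefore rest on single UMIs. No pair of libraries was close to sampling noise: chi-square per degree of freedom over genes was 97.5 for replicates 1 and 2, 74.1 for 1 and 3 and 21.6 for 2 and 3, so all 3 counted as separate libraries. Replicate 1 stood apart from the others in this measure.

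Feature rows are NCBI gene IDs with LOC symbols. Of 10903 IDs, 9712 were matched by ID to NCBI's RefSeq gene table of the assembly ASM2471394v1, and 2367 of those carry a symbol beyond a LOC number, which is mostly the symbol of a fruit fly counterpart. These 2367 genes hold 27.9% of the UMIs, and the 1191 unmatched IDs hold 8.69%. The deposited files name no build, so no coordinates are given. Genes of families with near-identical copies, such as cathepsins, tropomyosins and ribosomal proteins, can share reads, and how such reads were counted is not given in the sources used here. Their values are uncertain to that extent.

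Barcodes with at least 200 genes and a log UMI count within 5 median absolute deviations of the library median were kept. The filter removed 40 of 18861. The feature list has no mitochondrial genes, so no mitochondrial filter applied. Scrublet, with an expected rate of 0.06, marked 3 nuclei, which were removed. A caller that marks 0.0159% of the barcodes has not worked, so doublets remain in the data, and an added alternative removed the 6% of nuclei with the highest scores. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes, without any gene of the test lists, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Clusters with at least 20 nuclei in each library were tested.

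Raw counts were summed per library and cluster, since nuclei are not replicates. The 45 sums were fitted with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM scaling, filterByExpr and a term for the library. The library term stands because clusters of 1 library share a preparation: deviations from the cluster means correlated at a mean r across genes of 0.214 within a library (lowest 0.019 over 315 pairs) and -0.124 between libraries. Each cluster was compared with the mean of the log levels of the other 14, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change over 1 or under -1. An F-test asked whether a gene differs among clusters, and 9510 of 9608 tested genes did. Standard errors were taken as the fold change over the root of the F statistic. Intervals of shares are exact Clopper-Pearson at 95%.

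Gene lists were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated correlation, on log2 CPM with a prior count of 2, adjusted over all 120 pairs of a list and a cluster. In the 43 called pairs the median, the mean and the test had the same sign. They differed in sign, without a call, for the proteases in clusters 2 and 8, the transcription factors in 1, 6 and 12, the neuropeptides in 13 and the lipid genes in 2, 8 and 14. Counts adjusted over the list alone were those over all genes except for 1 more transcription factor higher in cluster 13, 1 fewer oxidative phosphorylation gene lower in cluster 13, and 1 more lower gene each for neuropeptides in cluster 14, innate immunity in 13 and lipid metabolism in 6.

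The lists, markers and the rule for named genes were fixed before the data were examined, as protein names. The RefSeq table gives symbols, so each was translated to fly symbols after the symbols and totals were seen and before any comparison of clusters. The detoxification, chitin and named-allergen lists matched 0 symbols. The tested lists hold 17 allergen family genes, 2 cysteine proteases and 0 serine proteases, 44 transcription factors, 12 genes of neuropeptides, their processing and their receptors (called neuropeptides here), 7 innate immunity genes, 56 ribosomal proteins, 38 genes of oxidative phosphorylation and 17 of lipid metabolism. Named genes are the 10 allergen family genes with the most UMIs, the 10 transcription factors with the largest rise (8 qualified) and the 5 with the largest fall that move the same way in all 3 libraries, and examples from the 3 members with the smallest adjusted p where camera calls a list. Other genes are named as cluster markers, or were chosen after their values were seen, as said beside them. No gene was named Der f 9, and the cluster with the highest summed CPM of the protease list was used in its place, as fixed for that case.

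The count test was tested on simulated data. Counts were drawn for the 9608 tested genes in the layout of the cluster 9 comparison, and 8889 were left after the filter on low counts. Changed genes lost to the filter count as missed. Only the changed genes differed between clusters, and no library effect was drawn. The real data are unlike this, with 9510 genes differing, so the rates need not hold there. An adjusted p under 0.05 was reached by 94% of genes changed 2-fold and 98% changed 4-fold upward. It was reached by 80% and 88% of those lowered to 0.5 and 0.25 of their level, and by 0.16% of unchanged genes. With the bound on fold change as well, as in the calls, these were 58%, 98%, 42%, 88% and 0.03%, so changes near 2-fold are often not called. Alternatives were DESeq2 1.42.0, no library term, no filter on low counts, other Leiden resolutions, all variable genes in the clustering, count splitting, doublets kept, a 500-gene minimum, thinning to 500 UMIs, each library left out, a comparison with all other nuclei and, for shares, genes centred per library before the principal components. The closing section gives their effect. Of the snATAC table, total, duplicate, TSS and peak counts were used.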

Results

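Nuclei of untreated whole house dust mites (Dermatophagoides farinae, an arachnid whose proteins are common indoor allergens) were profiled by single-nucleus RNA sequencing (snRNA) in 3 libraries and by single-nucleus ATAC sequencing (snATAC), which reads open chromatin, in 1 library. All 4 libraries belong to untreated mites, so the comparisons are between groups of nuclei within the snRNA libraries. Per the series' design text, the study asked which cell types express allergen genes and which transcription factors are candidates for regulating Der f 9, a mite allergen that is a serine protease. The snRNA libraries of replicates 1, 2 and 3 held 8452407, 16028945 and 12521558 unique molecular identifier (UMI) counts in 5243, 6999 and 6619 barcodes. The median barcode held 1007, 1373 and 1162 UMIs and 711, 843 and 749 genes, respectively. Of the 18861 barcodes, 18821 passed the filter used here, 18818 remained after 3 marked doublets were removed, and 15338 of these had at least 500 genes, beside the 16335 nuclei the study states. The labels' protocols describe nuclei pooled from 3 replicates, while the series' design text speaks of 3 biological replicates. Whether the libraries come from separate cultures is unclear, so the p-values and SDs below measure the spread between these libraries, which may be technical.

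The nuclei formed 18 clusters, of which 15 had at least 20 nuclei in each library and entered the tests. Cluster 8 was muscle-like: 12 of 13 muscle markers were higher there than in the other clusters, led by bt, a titin-like kinase of the sarcomere, at 33920 ± 4124 CPM (UMI counts of the sum scaled to a common depth; SD, n = 3), and by the myosin heavy chain Mhc at 16220 ± 1209 CPM. Cluster 2 was neuron-like, with 14 of 16 neuron markers higher, among them ChAT, which makes acetylcholine, at 838 ± 138 CPM, and Gad1, which makes GABA, at 504 ± 52.8 CPM. Clusters 12 and 13 were proliferating-like, with 9 of 18 markers higher in each. The mitotic cyclin CycB stood at 503 ± 91.7 CPM in cluster 12 and 64.1 ± 13.9 CPM in cluster 13, and the condensin subunit glu at 372 ± 116 CPM in cluster 13.

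Clusters 1 and 6 were basement membrane-like, with 5 of 6 markers higher in each. The other marker, trol, was lower in both, at 5.29 ± 3.35 CPM in cluster 1 and 6.77 ± 5.35 CPM in cluster 6. Its level was highest in cluster 7, at 194 ± 55.7 CPM. The type IV collagen gene Col4a1 stood at 5935 ± 3020 CPM in cluster 1 and 18020 ± 8542 CPM in cluster 6, and the laminin gene LanA at 779 ± 97.4 and 1029 ± 140 CPM. In cluster 1, both hemocyte markers (Tg and mew) and 2 of 4 vitellogenic and fat storage markers were also higher. In cluster 6, 3 of 4 vitellogenic and fat storage markers were also higher, with the fatty acid synthase FASN1 at 1978 ± 649 CPM. In cluster 8, 8 of 16 neuron markers were also higher, with the potassium channel gene Sh at 913 ± 83.5 CPM against 968 ± 127 CPM in cluster 2. Cluster 4 had 8 of 13 muscle markers higher and was left unnamed, since 6 of these 8 stood higher in cluster 8 in CPM. Clusters 5 and 10 had 4 of 5 tested germline markers higher and cluster 9 had 3 of 5. All 3 were left unnamed, since qin, a gene of the piRNA pathway, was lower in each, at 2.995 ± 1.17 CPM in cluster 5, 1.95 ± 1.76 CPM in cluster 10 and 0.518 ± 0.897 CPM in cluster 9. These grounds were not applied to clusters 1 and 6, which kept their name although trol was lower in both. Cluster 1 kept it although LanA, LanB1, wb and Col4a1 stood higher in cluster 6 in CPM. The names of clusters 1 and 6 are therefore less firm. Names rested on clusters with at least 50% of a class's markers higher, a bound set after the values were seen. Clusters 1 and 6 also met this bound for vitellogenic and fat storage markers (2 and 3 of 4), and cluster 8 for neuron markers (8 of 16). Their names give only the class with the larger part of its markers higher, so they leave out a second class that qualified. Classes with at most 3 tested markers gave no name, also decided after the values were seen. These were glia, with 2 of 3 markers higher in cluster 11, hemocytes, with 1 of 2 higher in clusters 0, 7 and 9, epidermis, whose only marker kkv was higher in clusters 0, 7, 12 and 13, and digestive cells, whose only marker cathD was higher in clusters 3 and 5. The clusters below are compared by number. The marker genes took part in the clustering and are given as descriptions of the clusters only.

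Cluster 0 held 18.2 ± 8.86% of a library's nuclei (SD, n = 3), cluster 1 held 16.5 ± 2.89%, the neuron-like cluster 2 held 11.2 ± 1.99% and the muscle-like cluster 8 held 4.48 ± 2.51%. In percentage points, the libraries differed most in cluster 0, which held 28.3% of the nuclei of replicate 1 (exact Clopper-Pearson 95% interval 27.1% to 29.6%), 12.04% of replicate 2 (11.3% to 12.8%) and 14.2% of replicate 3 (13.3% to 15.03%). Cluster 11 held 0.440% of replicate 1 (0.279% to 0.659%), 3.31% of replicate 2 (2.90% to 3.75%) and 2.62% of replicate 3 (2.25% to 3.04%). Cluster 8 held 1.80% of replicate 1, 6.77% of replicate 2 and 4.86% of replicate 3. The share differed more than 1.5-fold between libraries in 8 of the 15 clusters, in 4 without replicate 3 and in 0 without replicate 1. No test was run on shares, since the 3 libraries form 1 group, and the intervals cover counting error only.

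**Figure D1:**
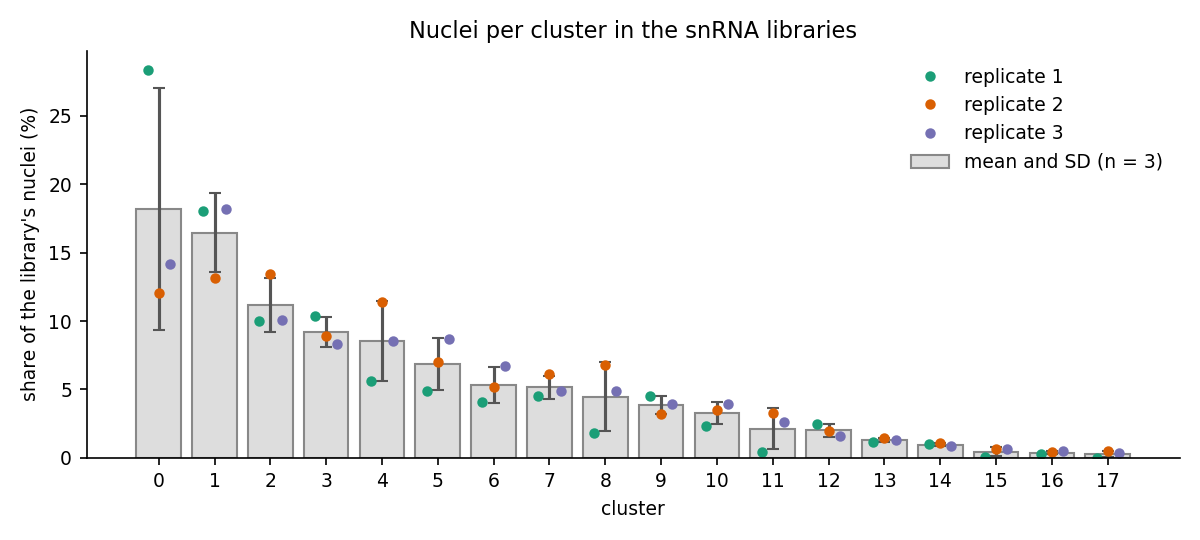
Share of each library's nuclei (percent) in each of the 18 clusters, with a point per snRNA library, bars at the mean and error bars of 1 SD (n = 3). Cluster 0 lies at 28.3% in replicate 1 against 12.04% and 14.2% in replicates 2 and 3.

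Genes of protein families that hold mite allergens differed widely among clusters, and the muscle proteins among them were concentrated in clusters 3, 4 and 8. The tropomyosin gene Tm1 (LOC124494125) reached 1232 ± 157 CPM in cluster 4 (log2 fold change 2.67, SE 0.109, edgeR adjusted p = 5.95e-35) and 1210 ± 423 CPM in the muscle-like cluster 8 (3.26, SE 0.117, adjusted p = 1.05e-38), against 26.9 ± 3.66 CPM in cluster 9. The paramyosin gene Prm (LOC124498392) reached 1829 ± 119 CPM in cluster 8 (3.95, SE 0.101, adjusted p = 1.51e-48) and 1204 ± 458 CPM in cluster 4, against 49.2 ± 12.9 CPM in cluster 7. The myosin light chain gene Mlc1 (LOC124498147) stood at 473 ± 163 CPM in cluster 4 (2.998, SE 0.128, adjusted p = 1.26e-33), 461 ± 129 CPM in cluster 8 and 344 ± 162 CPM in cluster 3, against 10.4 ± 4.07 CPM in cluster 9. Muscle markers were higher in the same clusters, 6 of 13 in cluster 3, 8 in cluster 4 and 12 in cluster 8. All 17 tested genes of these families differed among the 15 clusters in the F-test, as did 9510 of all 9608 tested genes, so this is not particular to the families.

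Among enzymes and housekeeping proteins of the same list, cluster 5 held the highest level of the profilin gene chic (LOC124498373) at 1114 ± 55.3 CPM (log2 fold change 1.67), of the fructose-bisphosphate aldolase gene Ald1 (LOC124499704) at 1211 ± 556 CPM (2.16), of the RutC family gene UK114 (LOC124497233) at 320 ± 86.4 CPM (2.57) and of the inorganic pyrophosphatase gene Nurf-38 (LOC124497071) at 170 ± 53.6 CPM (1.95). The cofilin gene tsr (LOC124492928) was highest in cluster 3 at 460 ± 19.6 CPM (1.33), the thioredoxin gene Trx2 (LOC124496008) in cluster 11 at 809 ± 231 CPM (1.52) and the heat shock 70 family gene Hsc70-5 (LOC124493118) in cluster 13 at 390 ± 75.7 CPM (1.24). CPM values are not TMM-scaled, while the fold changes are, so they can rank clusters differently. By fold change, Hsc70-5 was higher in clusters 0 (1.59) and 7 (1.57) than in cluster 13. Likewise, Mlc1 (3.57) and Tm1 (3.26) were higher in cluster 8 than in cluster 4. Each of the 10 named genes was higher in all 3 libraries at its peak in CPM, with edgeR adjusted p-values of at most 9.80e-10. The peak was chosen from the same libraries, so being higher there is largely by construction. The p-values are not adjusted for this choice. Trx2 lost its call in cluster 11 at a Leiden resolution of 1.0 (log2 fold change 0.67) and of 0.3 (0.94). At 0.3, cluster 11 has no counterpart of its own: its best match, at a Jaccard index of 0.123, is also that of cluster 2 (0.606), so 0.94 is the value of a merged group.

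Over the 255 pairs of a gene and a cluster, 49 were higher and 51 lower, and the counts adjusted over the list alone were the same. Clusters 3 and 4 each had 8 of 17 genes higher and 0 lower. Clusters 9 and 10 each had 10 genes lower, beside 5 and 3 higher. Clusters 0 and 7 each had 7 lower and 1 higher. As a list, the families were called higher by camera in cluster 3 (adjusted p = 3.17e-10, and adjusted p = 8.81e-05 with an estimated correlation), in cluster 4 (4.46e-08, and adjusted p = 0.000237 with an estimated correlation) and in cluster 14 (0.00118, and adjusted p = 0.0344 with an estimated correlation), where 1 of the 17 genes passed on its own. The list's calls in clusters 8 and 11 (higher) and 0, 1, 7 and 10 (lower) were lost with an estimated correlation, at adjusted p = 0.0807, 0.118, 0.0807, 0.0807, 0.0678 and 0.109 with an estimated correlation, respectively. A family symbol does not show that a gene encodes a registered allergen: 0 of the matched genes carry an allergen name.

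**Figure D2:**
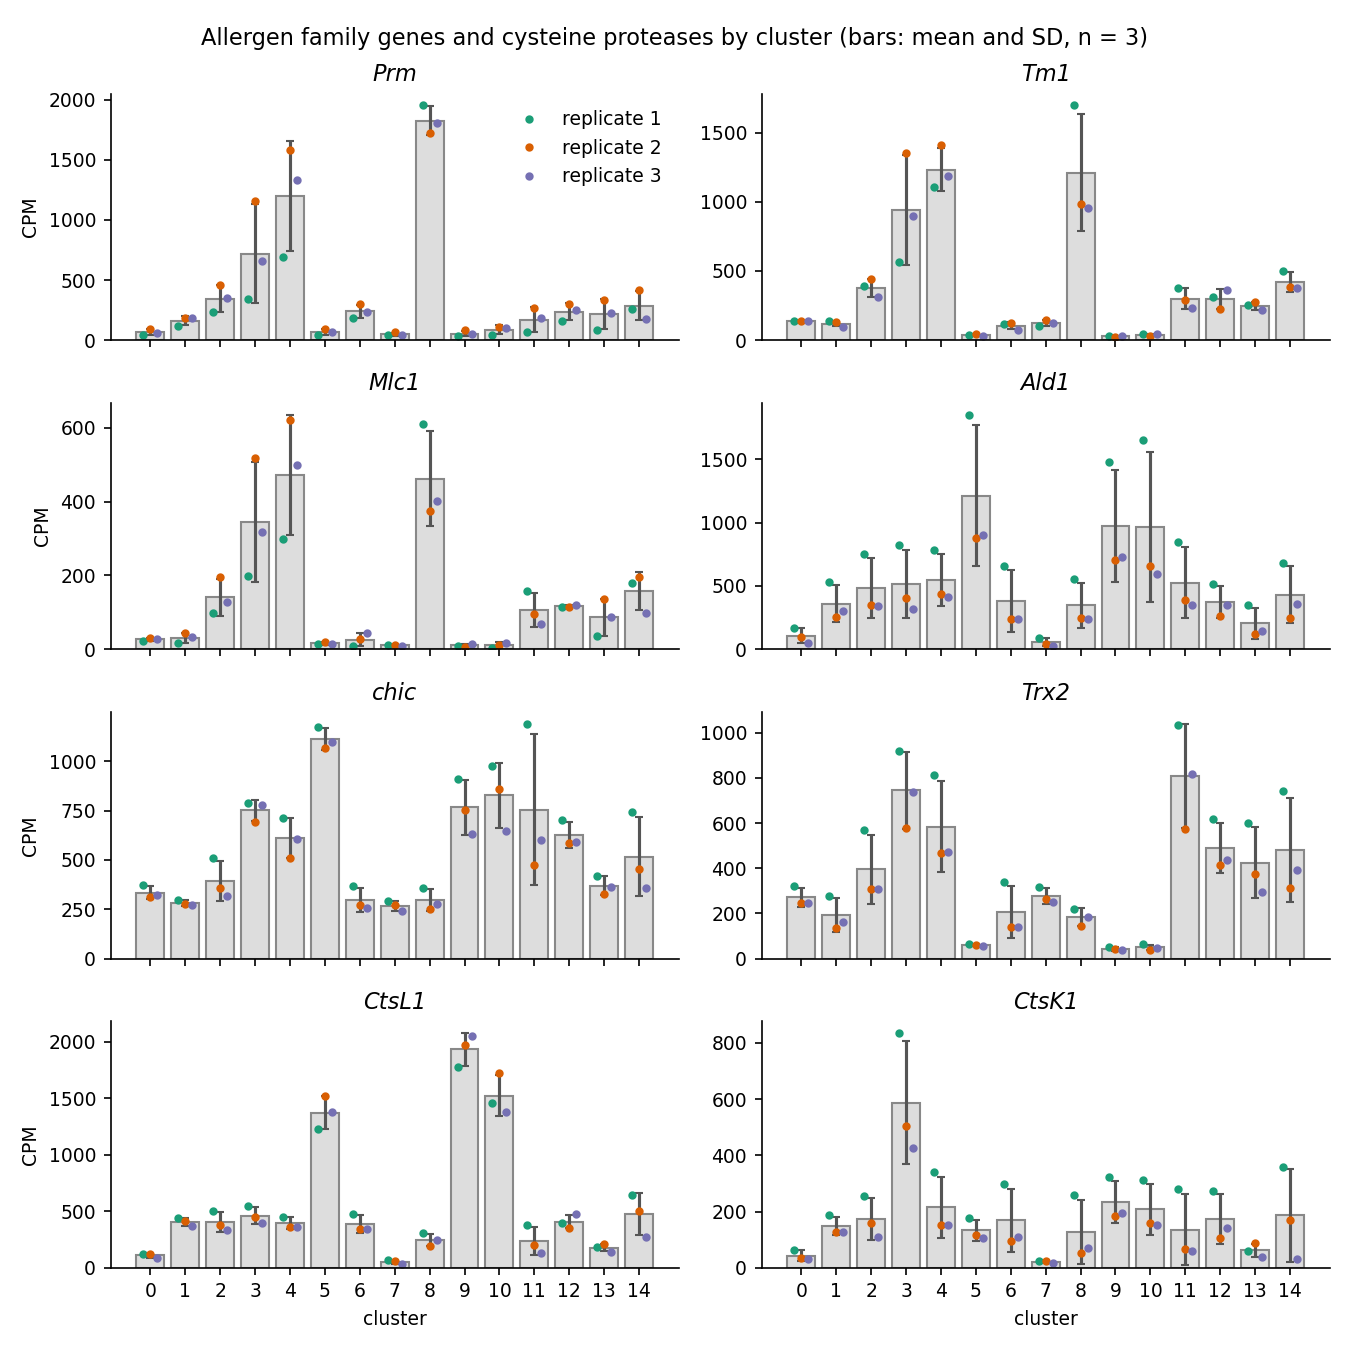
CPM in the 15 tested clusters for 6 genes of allergen families and the cysteine proteases CtsL1 and CtsK1, with a point per snRNA library, bars at the mean and error bars of 1 SD (n = 3). Prm, Tm1 and Mlc1 are highest in clusters 3, 4 and 8, and CtsL1 in clusters 5, 9 and 10.

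No gene was named Der f 9, so the transcription factors were compared in the cluster with the highest summed level of the protease list, as set for this case before the data were examined. That list held 2 cysteine protease genes and 0 serine proteases, and both genes were named because they choose the cluster. Der f 9 is a serine protease, so cluster 9 and its factors do not show where Der f 9 is expressed or what regulates it. CtsL1 (LOC124493587), a cathepsin L, reached 1931 ± 144 CPM in cluster 9 (log2 fold change 2.91, SE 0.089, edgeR adjusted p = 2.64e-43) and was higher in all 3 libraries. Its level helped to choose the cluster, so these values describe the choice and do not test it. CtsK1 (LOC124499492), a cathepsin K-like gene, was highest in cluster 3, at 588 ± 218 CPM (2.16, SE 0.112, adjusted p = 1.07e-28). Their summed level was 2165 CPM in cluster 9, 1728 CPM in cluster 10, 1506 CPM in cluster 5 and 1050 CPM in cluster 3. Camera called the protease list lower in clusters 0, 7 and 13, with CtsL1 at 110 (log2 fold change -1.72), 54.8 (-2.93) and 179 CPM (-1.70). These calls were lost at adjusted p = 0.192, 0.115 and 0.109 with an estimated correlation.

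Of 43 tested transcription factors, 6 were higher in cluster 9, 18 were lower and 19 were not called, with 6 higher and 18 lower when adjusted over the list alone. Of all 9608 tested genes, 2883 were higher and 2311 lower in this cluster. The factors were thus less often higher, and more often lower, than genes at large. The nuclear receptor gene Hr96 (LOC124497919), whose fly counterpart acts in lipid and xenobiotic responses, stood at 476 ± 162 CPM against a mean of 187 CPM in the other clusters (log2 fold change 2.12, SE 0.097, edgeR adjusted p = 1.62e-32). Atf6 (LOC124499591), a factor of the endoplasmic reticulum stress response, stood at 206 ± 30.5 CPM against 66.6 CPM (2.10, SE 0.117, adjusted p = 2.12e-27). Of the 6, these were the ones whose level was highest in cluster 9 among the 15 clusters. The homeobox gene mirr (LOC124491667) stood at 957 ± 202 CPM (1.40, SE 0.107, adjusted p = 3.64e-20) but at 3010 ± 518 CPM in cluster 1, and eya (LOC124499589) at 106 ± 16.3 CPM (1.12, SE 0.143, adjusted p = 7.87e-11) but at 538 ± 91.5 CPM in cluster 1. Nf-YA (LOC124497747), a subunit of a CCAAT-binding complex, stood at 17.6 ± 3.78 CPM (1.24, SE 0.335, adjusted p = 0.000682) and vnc (LOC124498465) at 26.9 ± 10.9 CPM (1.16, SE 0.227, adjusted p = 5.45e-06). REPTOR-BP (LOC124496819) at 43.2 ± 16.1 CPM and a log2 fold change of 0.95, and ush (LOC124498237) at 129 ± 14.5 CPM and 0.83, stayed under the bound on fold change. All 8 were higher than the mean of the other clusters in all 3 libraries, which was a condition for naming them and not a separate result.

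The 5 largest falls among called factors in cluster 9 were as follows, taken only from factors lower in all 3 libraries. SoxN (LOC124491687) stood at 1.59 ± 1.55 CPM (log2 fold change -4.06, SE 0.407, edgeR adjusted p = 1.21e-14), Ets65A (LOC124492062) at 1.15 ± 0.452 CPM (-3.60, adjusted p = 8.30e-10), zfh2 (LOC124495212) at 14.99 ± 3.85 CPM (-3.21, adjusted p = 4.94e-23), pros (LOC124497439) at 6.01 ± 3.47 CPM (-3.04, adjusted p = 2.15e-17) and Hr38 (LOC124499377) at 0.944 ± 1.04 CPM (-2.92, adjusted p = 1.40e-05), each lower in all 3 libraries. The fitted changes of the genes near 1 CPM depend on the prior count. As a list, the factors were called lower in cluster 9 by camera (adjusted p = 0.0122), a call lost at adjusted p = 0.301 with an estimated correlation. Against the summed counts of all other nuclei, 3 factors were higher in place of 6: Hr96, Atf6 and vnc kept their calls, and the log2 fold changes of mirr, Nf-YA and eya were 0.65, 0.75 and 0.10. Over 15 alternatives, eya lost its call in 9 and kept it in 6, so it is not a firm result. The call was also lost under count splitting for mirr (0.93), without replicate 2 for Nf-YA (0.99) and without replicate 3 for vnc (0.93).

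**Figure D3:**
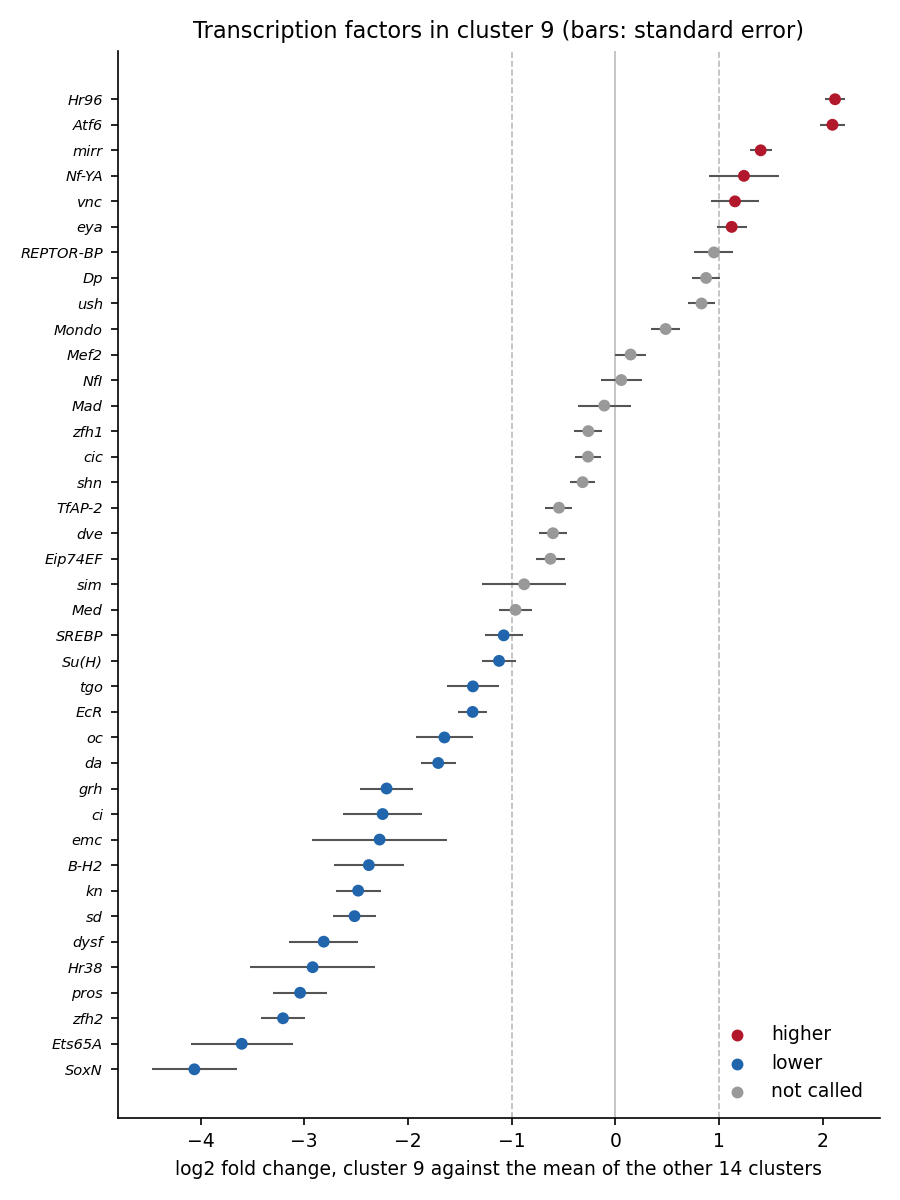
Log2 fold change of 39 transcription factors in cluster 9 against the mean of the other 14 clusters, with bars of 1 standard error and dashed lines at the bounds of -1 and 1. The 6 factors called higher run from eya at 1.12 to Hr96 at 2.12, and SoxN lies lowest at -4.06. The factors crp, slou, Hr3 and hb, whose standard error was very large or could not be computed, are not drawn.

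Of the list of neuropeptides, their processing and their receptors, 9 of the 11 tested genes were higher in the neuron-like cluster 2 and 0 lower, the receptor gene rk among the 9. The secretory chaperone gene 7B2 stood at 814 ± 192 CPM (log2 fold change 3.71, edgeR adjusted p = 5.68e-47), the diuretic hormone gene Dh31 at 337 ± 113 CPM (3.64, adjusted p = 1.25e-35) and the myoinhibitory peptide gene Mip at 346 ± 111 CPM (2.89, adjusted p = 1.41e-32). Camera called the list in this cluster with the preset correlation (adjusted p = 4.73e-09) and at adjusted p = 0.000133 with an estimated correlation. The transcription factors were also called higher in cluster 2, with 14 of 43 higher and 0 lower (adjusted p = 0.000146), a call lost at adjusted p = 0.118 with an estimated correlation. They were called lower in cluster 5, with 20 of 43 lower (adjusted p = 0.273 with an estimated correlation), and in cluster 10, with 19 lower (adjusted p = 0.303 with an estimated correlation).

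Ribosomal protein transcripts were low in clusters 5, 9 and 10, where 45, 43 and 52 of 56 genes were lower and the median log2 fold changes were -1.79, -1.78 and -1.91. RpL24, of the large subunit, stood at 33.2, 33.4 and 33.4 CPM in these clusters (log2 fold changes -2.60, -2.61 and -2.61). The median nucleus held 2620.5, 3035 and 2608 UMIs in clusters 5, 9 and 10, beside 3143 in cluster 7 and 1183 over all barcodes. The genes were also lower in clusters 1 and 6 (30 and 36 of 56). They were higher in clusters 3, 7, 11 and 0 (39, 41, 38 and 37 of 56), with RpLP1 at 1452 CPM in cluster 3 (1.64) and RpL3 at 4410 CPM in cluster 0 (1.80). Camera called the list in 14 of the 15 clusters with the preset correlation, and in cluster 3 alone with an estimated one (adjusted p = 0.0253 with an estimated correlation). In clusters 5, 9 and 10 the calls were lost at adjusted p = 0.0807, 0.0807 and 0.0678 with an estimated correlation, and in the other 10 clusters at adjusted p-values between 0.0675 and 0.415 with an estimated correlation. Cluster 8 had 1 of 56 lower, RpL36A at 100 CPM (-1.01), and the list's call there (lower) was lost under count splitting (adjusted p = 0.791) and without the 6% of nuclei with the highest Scrublet scores (adjusted p = 0.735). It turned to higher at a Leiden resolution of 0.3, where clusters 4 and 8 share 1 best match.

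Genes of oxidative phosphorylation were higher in clusters 3 and 4, with 12 of 38 higher and 0 lower in each. ATPsynC, a subunit of the ATP synthase, stood at 475 CPM in cluster 3 (log2 fold change 1.53, edgeR adjusted p = 2.74e-21) and 544 CPM in cluster 4 (1.71, adjusted p = 2.15e-24). The list was called higher in clusters 3, 4, 11, 12 and 14 and lower in clusters 0, 1, 6, 7 and 10, and all 10 calls were lost with an estimated correlation (adjusted p from 0.0807 in cluster 3 to 0.465 in cluster 12 with an estimated correlation). Genes of lipid metabolism were higher in the basement membrane-like cluster 6, which also had 3 of 4 vitellogenic and fat storage markers higher. In this cluster 7 of 17 lipid genes were higher and 1 lower. The acetyl-CoA carboxylase gene ACC stood at 1943 ± 241 CPM (1.62), the lipase gene Hsl at 218 ± 77.7 CPM (1.83) and the acyl-CoA dehydrogenase gene Acadvl at 261 ± 45.5 CPM (1.47). The list was called higher there (adjusted p = 0.00393, and adjusted p = 0.0691 with an estimated correlation) and lower in cluster 13 (adjusted p = 0.0113, and adjusted p = 0.0807 with an estimated correlation), where 3 of 17 were lower. Lipid genes were also higher in clusters 5, 9 and 10 (8, 6 and 6 of 17, beside 3, 4 and 1 lower), without a call of the list. Of all 9608 tested genes, 2909, 2883 and 2653 were higher in these clusters, so higher genes were common there at large. For innate immunity, with 6 tested genes, camera called 0 of the 15 clusters with either correlation, with 2 clusters at an unadjusted p under 0.05 with the preset correlation and 0 with an estimated one, and DESeq2 scaling also gave 0 clusters but a Leiden resolution of 1.0 gave 1 with the preset correlation, while 14 pairs of a gene and a cluster were higher and 10 lower. In all, camera called 43 of 120 pairs of a list and a cluster with the preset correlation, 21 higher and 22 lower, and 5 with an estimated one. Random regroupings of the cluster sums gave 15 to 36 preset calls, with a median of 25, though they mix unlike sums and are no plain rate of false calls. With simulated counts in the layout of cluster 9, the preset test called 0 of 20 lists of unchanged genes. Those genes were drawn independently, so the simulation cannot show how often the preset test calls lists of correlated genes.

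In the snATAC library, 7247 barcodes were called nuclei in the deposited table, beside the 7150 nuclei the study states. These barcodes held 86720572 fragments that passed filters, 64.6% of the fragments of all barcodes, with a median of 6872 per nucleus (quartiles 1301 and 16505). Fragments overlapping transcription start sites made up 60.5% of those in called nuclei (exact Clopper-Pearson 95% interval 60.5% to 60.5%) and 61.5% of those in the other 516319 barcodes. Fragments in peaks made up 34.5% (34.4% to 34.5%) in called nuclei and 37.3% (37.3% to 37.4%) in the other barcodes, while the median share per barcode went the other way, at 39.5% and 31.4%. The other barcodes held a median of 1 fragment, so their share per barcode rests on very few fragments. Among called nuclei, 1706 held under 1000 fragments, and 43.2% of their fragments lay in peaks, against 32.4% in the 2882 nuclei with at least 10000 and 44.9% in the 2659 between these bounds. The library has no replicate, so these differences were not tested, and the intervals cover counting error only. Accessibility at single genes was not analysed here.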

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

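No test was run on the values in this part, and the genes of the small clusters were chosen after their values were seen, as the named gene with the largest fold in each. They come from nuclei outside the 15 tested clusters, and from barcodes that the report gives no values of their own. In the snATAC library, 8104 barcodes that were not called nuclei held at least 1000 fragments, and 37.2% of their fragments lay in peaks (exact 95% interval 37.2% to 37.2%, counting error only), against 34.5% in called nuclei. The median share per barcode went the other way, at 37.1% against 39.5% in called nuclei. Of the 8104, 7956 carry exclusion code 3 in the deposited table, 143 carry code 1 and 5 carry code 2. What the codes mean is not given in the sources used here.

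Clusters 15, 16 and 17 held 92, 75 and 56 nuclei and were left out of the tests for having too few in at least 1 library. Cluster 15 held 4, 43 and 45 nuclei of replicates 1, 2 and 3, cluster 16 held 13, 30 and 32, and cluster 17 held 1, 33 and 22. In cluster 15, Nos, the nitric oxide synthase gene, stood at 1704 CPM from 237 UMIs (exact Poisson interval 1494 to 1936 CPM) against 37.2 CPM in all other nuclei and 88.7 CPM in cluster 7, the highest of the tested clusters. In cluster 16, the phosphoglucomutase gene Pgm2a stood at 380 CPM from 41 UMIs (272 to 515 CPM) against 40.6 CPM elsewhere and at most 129.5 CPM in a tested cluster (cluster 12). In cluster 17, the transcription factor gene sim stood at 396 CPM from 25 UMIs (256 to 584 CPM) against 10.4 CPM elsewhere and at most 120.5 CPM in a tested cluster (cluster 14), so sim is not particular to it. These intervals cover counting error only, and clusters are built on the same counts, so leading genes are high by construction.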

How the results depend on the processing

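Removing the 6% of nuclei with the highest Scrublet scores was chosen after the data were seen, as was the 1.5-fold summary of shares, and all other alternatives were fixed before. All 17 allergen family genes differed among clusters in the main analysis and 16 or 17 in each alternative. Gene and cluster pairs numbered 42 to 54 higher and 41 to 54 lower across the alternatives (49 and 51 in the main analysis), transcription factors in cluster 9 numbered 3 to 7 higher and 13 to 22 lower (6 and 18), and camera calls 19 to 28 up and 13 to 24 down (21 and 22). The low ends were 3 higher factors in the comparison with all other nuclei and 13 camera calls down with nuclei thinned to 500 UMIs, where fewer UMIs enter the test. With an estimated correlation, camera calls numbered 3 to 11 up and 0 to 7 down.

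Leaving out 1 library at a time gave 16 to 17 allergen genes differing, 47 to 51 pairs higher and 46 to 49 lower, 4 to 5 factors higher and 16 to 20 lower, and 19 to 21 camera calls up and 15 to 21 down. The allergen list lost its camera call in clusters 0, 1, 8, 10 and 11 without replicate 1 (adjusted p 0.0525, 0.0804, 0.0804, 0.0563 and 0.109). The number of clusters whose share differed over 1.5-fold ran from 0 without replicate 1 to 8 without replicate 2, against 8 with all libraries. It was 7 to 11 under other clusterings, and 7 with genes centred per library, where clusters 0 and 7 have the same best match (Jaccard index 0.729 and 0.235). Without the replicate block (the library term), 17 allergen genes differed, 50 pairs were higher and 51 lower, 7 factors were higher, REPTOR-BP being added at a log2 fold change of 1.02, and the allergen list lost its call in cluster 0 (adjusted p = 0.0678). No other preset camera call or named gene changed without the block.

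Of 370 values of named genes under the alternatives, 352 kept their direction and call, 16 lost it and 2 gained it. Of those 16, 9 were eya in cluster 9, at log2 fold changes of 0.10 to 0.98. Some kept values belong to matched groups that overlap little with the main cluster, so these totals overstate how firm the calls are. Hsc70-5 kept its call in 15 of 15 alternatives in cluster 13. That cluster matched at a Jaccard index of 0.054 at a Leiden resolution of 0.3 and 0.139 with all variable genes. The index was 0.112 under count splitting and 0.111 with a 500-gene minimum. List calls carry the same limit. Of 599 list calls in single clusters, 527 kept their call, 70 lost it and 2 changed sign. Those 2 were the ribosomal proteins in cluster 8, called lower in the main analysis and higher at a Leiden resolution of 0.3 (adjusted p = 8.82e-09), and higher without a call under count splitting (adjusted p = 0.791). At 0.3, clusters 4 and 8 have the same best match (Jaccard index 0.464 and 0.423), so that value is of a merged group, and the proteins were higher in cluster 4 (11 of 56). The change under count splitting was not traced. Of 448 allergen counts in single clusters, 87 moved by more than 1.5 times, and of 120 shares, 26 moved by more than 1 SD. Keeping the 3 marked doublets alone moved the borders between clusters, so single-cluster counts are less firm than totals.

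DESeq2 scaling shifted the median log2 fold change of all genes by -0.17, 0.12, -0.12, 0.15, 0.18 and 0.12 in clusters 1, 5, 6, 12, 13 and 14. The share of higher among called genes was 44.6% with edgeR and 27.1% with DESeq2 in cluster 1, 80.1% and 68.5% in cluster 4, 58.3% and 72.0% in cluster 12, 51.3% and 69.4% in cluster 13, and 63.2% and 89.8% in cluster 14. All 43 camera calls and all 25 named values kept their direction and call with it. A minimum of 500 fragments kept 16450 snATAC barcodes (5880 of them called nuclei), 1000 kept 13645 (5541) and 3000 kept 9188 (4859) against 7247 called nuclei, since the table's own call does not follow a fragment minimum. The snRNA nuclei numbered 18861 without a filter, 18821 with doublets kept and 15338 with 500 genes, against 18818.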

Other observations

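The tests of muscle transcripts in cluster 4, of nuclear depth and free RNA for the ribosomal proteins, and of the border between clusters 0 and 7 were chosen after the results were seen. The genes in the next paragraph were also chosen after their values were seen. The regroupings, the removal of abundant genes and the raised UMI minimum were fixed before their results, and the minima from the libraries' medians were added after.

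Of the 6 tested innate immunity genes, which stayed out of the clustering, IKKbeta and Myd88 were higher in clusters 5, 9 and 10, while camera called the list in none of these (adjusted p = 0.527, 0.260 and 0.324). IKKbeta, a kinase of the NF-kappaB pathway, stood at 482 ± 57.8, 455 ± 12.8 and 402 ± 28.1 CPM (SD, n = 3), and the adaptor gene Myd88 at 88.3 ± 11.5, 99.6 ± 17.5 and 112 ± 23.8 CPM. Each was higher in all 3 libraries (edgeR log2 fold changes 2.26 to 2.90). IKKbeta stood at 16.1 ± 3.12 CPM in cluster 7. The ion transport peptide gene ITP was also higher in clusters 5, 9 and 10, at 297 ± 48.1, 149 ± 32.6 and 222 ± 50.6 CPM. The thioester protein gene Tep2 was higher in the basement membrane-like clusters 1 and 6, at 397 ± 125 and 449 ± 180 CPM, against 25.2 ± 8.47 CPM in cluster 7. The neuropeptide gene sNPF was higher outside the neuron-like cluster as well, at 304 ± 15.7 CPM in cluster 6 and 174 ± 44.1 CPM in cluster 10 against 187 ± 13.4 CPM in cluster 2. Clusters 0 and 7 shared high levels of the ryanodine receptor gene RyR (1492 ± 52.4 CPM in cluster 0) and of form3 (459 ± 18.7 and 533 ± 21.8 CPM), and were the clusters with the lowest level of the proteases (154 and 77.4 CPM).

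Chance was tested by regrouping the cluster sums at random within each library, with 50 groupings drawn, the real one included. For the allergen family genes that differ among clusters, 1 of the 50, the real one, reached 17, and the highest other gave 3. For their higher or lower pairs, 1 of the 50 reached 100, and the highest other gave 11. For the transcription factors in cluster 9, 1 of the 50 reached 24, and the highest other gave 13. For camera calls with the preset correlation, 1 of the 50 reached 43, and the highest other gave 36. The real grouping thus gave the most of each count, but this cannot exclude chance. The clusters were built jointly from the 3 libraries, so their match between libraries is by construction. A regrouping also mixes unlike sums and so widens the spread within groups. For single camera calls with the preset correlation chance stays open as well, since other groupings gave a median of 25 calls.

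Muscle transcripts in cluster 4 are the first pattern. The summed CPM of all 16 tested muscle genes, called or not, was at least 6.33 times that of cluster 1, whose nuclei have similar depth, in each library, which argues against free RNA as the whole source, since that gives like levels to both. Nuclei of the muscle-like cluster 8 mixed into cluster 4 would bring its transcripts in 1 ratio. Among the 11 muscle genes higher in cluster 4, and after the level in cluster 1 was subtracted from each, the highest ratio of cluster 4 to cluster 8 was at least 12.97 times the lowest in each library. Before subtraction, Mp20 stood at 1030 CPM against 624 and bt at 4446 against 33920. CPM are not TMM-scaled: by fold change, Mp20 was nearly alike in clusters 4 and 8 (3.40 and 3.33), while bt was not (2.54 and 6.41). The unequal ratios argue against mixing as the whole source only. Mixing as a part of the source stays open, since doublets remain in the data. The summed CPM of the 16 genes in cluster 4 was 11280, 21490 and 18950 in replicates 1, 2 and 3. These values rank like the share of cluster 8 in the libraries (1.80%, 6.77% and 4.86%). A separate muscle-expressing population is a further hypothesis, and no biological explanation was tested, since the design has 1 group.

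The low ribosomal protein transcripts of clusters 5, 9 and 10 are the second pattern. Nuclear depth argues the other way: cluster 7, as deep as these, had a median log2 fold change of 1.22. Free RNA would give each nucleus a like number, and cluster 7 held 119 ribosomal protein UMIs per nucleus, 5.17 times the highest of the 3 clusters (23.0), which argues against it for the difference from cluster 7. For the difference from the shallower clusters 1, 2, 6 and 8 free RNA stays open: these held 11.01, 17.02, 11.45 and 10.66 per nucleus, beside 18.6, 23.0 and 15.8 in clusters 5, 9 and 10, and the ratio of the means was 1.10, 1.83 and 1.59 in replicates 1, 2 and 3, which does not settle whether the numbers are alike. The other shallower clusters, 0, 3, 4, 11, 12, 13 and 14, held 29.03 to 62.41, more than clusters 5, 9 and 10. These values were not split by library. Clusters 11 and 12, at 51.58 and 62.41, argue against free RNA for the difference from them. For the others, at 29.03 to 44.29 beside 23.0 in cluster 9, free RNA stays open, as for clusters 1, 2, 6 and 8. A few genes taking most of the counts were not found: the 50 most abundant genes held 26.2%, 24.7% and 24.7% of the UMIs in clusters 5, 9 and 10. Without the 50 most abundant genes of each of the 3 clusters, the medians were -1.77, -1.77 and -1.89. Removing so small a share could move the medians only a little, so the removal itself could hardly have come out otherwise. No biological explanation was tested.

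The high share of cluster 0 in replicate 1 is the third pattern. The UMI minimum was raised to 638 and 536 in replicates 2 and 3, by the median over the 15 clusters of the ratio of a cluster's median UMIs to that in replicate 1. The shares of cluster 0 were then 12.4% and 14.3%, still far under 28.3%, and 12.4% and 14.6% with minima of 682 and 577 from the ratio of the libraries' medians, which argues against depth under a shared minimum. The border with cluster 7 does not account for it either, since the summed share of clusters 0 and 7 in replicate 1 was at least 1.72 times that of the other libraries (32.8% against 18.1% and 19.0%). The labels give no batch, and a difference in dissociation or in the mites sampled stays open as a candidate explanation that these data could not test.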
